A study of Homo sapiens with 6 samples.

How the data were processed

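The study compared RNA of irradiated CloneK cells with RNA of unirradiated Clone10 cells on spotted cDNA arrays, with both RNAs on each array in different dyes. Part A and part B of the array set were each hybridised 3 times. Per the labels, CloneK was labelled with Cy3 and Clone10 with Cy5 on replicate 1, and CloneK with Cy5 and Clone10 with Cy3 on replicates 2 and 3. Total RNA of different batches was pooled before labelling, per the labels.

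The deposited values are log2 ratios of the 2 channels of an array, as the authors normalised them. Per the labels, the slides were scanned with ScanArray Express and quantified with QuantArray 3.0, and the macro Normaliser2 removed spots with a signal under 2.5 times the subarray background, spots under a 5% limit of intensity and streaked or damaged spots. The background was subtracted and the log2 ratio normalised by regression within each subarray, per the labels. The numerator of the ratio and a genome build are not given in the sources used here. Intensities were not used here, so signal over background could not be set beside a ratio. Regression within subarrays centres each subarray, so a change shared by most spots of a subarray would be removed.

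The median log2 ratio of replicates 1, 2 and 3 was -0.08, -0.04 and 0.02 in part A and -0.02, 0.01 and 0.01 in part B. The SD over spots was 0.69, 0.78 and 0.51 in part A and 0.56, 0.55 and 0.52 in part B. Between 0.724% and 4.44% of the spots of an array had no value. Between 5.45% and 17.4% of the spots with a value lay beyond 2-fold. The scale of the values is given by the labels, and their medians lie near 0. The direction is unknown for replicate 1 and likely for replicates 2 and 3.

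The rule for the direction was fixed before the data were examined. Replicate 1 was to be used as deposited where its Pearson correlation with the mean of replicates 2 and 3 reached 0.1, turned where it reached -0.1, and left out of signed results in between. The correlation was 0.068 over 18287 spots in part A and -0.066 over 17516 spots in part B, so signed results rest on replicates 2 and 3. The gene lists, the tests, the rule for named genes and the alternatives were also fixed before the data were examined. Each part was fitted alone, since the parts carry different clones and were normalised separately.

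Spots were named through the platform annotation, with symbols updated by gene identifier from RefSeq annotation of GRCh38.p14, which was used only for names and chromosomes. In part A, 7872 of 19200 spots had 1 gene symbol, 346 had several and 10982 were not named here. In part B the numbers were 8000, 312 and 10888. The gene identifiers of 7864 and 7992 spots were found in that annotation. No gene was named from a spot with several symbols. Spots with a value on all 3 arrays of a part were used. Spots of one clone were averaged, then the clones of one gene, and spots without a clone identifier were kept alone.

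The mean log2 ratio of each feature was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over all features of the part and a threshold of 0.05. A count of features with one sign on the arrays used and a mean of at least 2-fold was given without a test. Of 27 gene lists, those with at least 5 measured members in a part were tested with camera at a preset correlation of 0.01, and chromosomes with at least 20 genes in the same way. Pearson's r and Spearman's rho between parts were tested with 100000 permutations, 2-sided. Tables were joined with pandas 2.3.3 and plots drawn with matplotlib 3.10.9.

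The named genes followed a rule. Genes past the threshold with one sign on all arrays used were to be named first, and none passed. The text then gives the 3 highest and the 3 lowest means of one sign in each part, up to 2 members of each tested list with the largest mean of one sign, and CDKN1A, MDM2, GADD45A, FOS, JUN, EGR1, ATM, PRKDC and XRCC5 where measured. The values of 1 further gene list and 1 further preset gene are not reported here.

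The alternatives were the addition of replicate 1 with either sign, a dye term, centring and scaling of the arrays, spots with values on at least 2 of 3 arrays, each spot alone, robust eBayes, no moderation, each array left out in turn, a 1.5-fold threshold, camera with an estimated correlation, and fry. The test was also tried on simulated data. The values of each array were shuffled over the real features, 200 features were changed by a known fold, and this was run 5 times per fold. With 2 arrays and no change, limma passed 4.2 features per run in part A and 0 in part B. With 200 features changed 4-fold it passed 20.4 and 2.4 unchanged features per run. With no shift and genes made unrelated by the shuffling, camera passed 0.455% of the list tests in part A and 0% in part B.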

Results

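Transcript levels in irradiated CloneK cells were compared with those in unirradiated Clone10 cells on 6 cDNA arrays with 2 colours each. HCT116 is a human colorectal carcinoma cell line. CloneK is a clone of it that is sensitive to X-rays, and Clone10 is a clone whose response to X-rays resembles that of the parental line. RNA of CloneK was collected 10 min after a dose of 4 Gy. The comparison asks which transcripts differed between the sensitive clone shortly after irradiation and the control clone without irradiation. No array separated the effect of the clone from that of the irradiation, so each difference below covers both.

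The clones of the array set were printed on 2 slides, part A and part B, with 19200 spots each, and each part was hybridised 3 times (replicates 1, 2 and 3). The number of arrays limits the precision of every value. Replicate 1 carried the reciprocal labelling, and the direction of its ratios could not be settled from the labels or the values. Signed values below are therefore means over replicates 2 and 3 (± SD, n = 2). Both carried CloneK in Cy5 and Clone10 in Cy3, so a dye bias of a gene cannot be told apart from a difference between the RNAs. A positive value is likely higher in CloneK, since both CloneK over Clone10 and Cy5 over Cy3 give that direction, although the labels do not name the numerator and the opposite remains possible. The RNA was pooled from different batches, so the arrays may be repeated hybridisations of the same RNA. In that case the p-values measure only the spread between hybridisations. The values of single genes below rest on replicates 2 and 3 together. With replicate 1, as deposited or turned, in place of replicate 2 or 3, 36 of 67 values of named genes took the opposite sign in at least 1 of these 4 settings. Both signs of replicate 1 were tried and only 1 can hold, so this count can overstate the changes. In a single setting, between 9 and 16 values took the opposite sign.

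In part A, the genes with the highest mean log2 ratio and one sign on replicates 2 and 3 were PTPRG-AS1, SMIM15 and MINDY2. PTPRG-AS1, an antisense RNA of the phosphatase gene PTPRG on chromosome 3, had a log2 ratio of 1.55 ± 0.86 (SD, n = 2), or 2.93-fold. A spotted cDNA does not separate it from a transcript of the other strand. SMIM15, a small membrane protein gene, stood at 1.55 ± 1.76, and MINDY2, a deubiquitinase gene, at 1.44 ± 1.40. At the low end were VPS35, a core subunit of the retromer that sorts endosomal cargo, at -1.39 ± 1.31, STARD10, a phospholipid transfer protein, at -1.29 ± 1.34, and FAT4, an atypical cadherin, at -1.29 ± 0.27. FAT4 was the only one of these 6 genes with both replicates beyond 2-fold, at -1.10 and -1.48. Replicate 1, as deposited, read -3.39 for FAT4, -1.97 for MINDY2, -0.46 for PTPRG-AS1, -0.44 for STARD10, -0.12 for VPS35 and 0.01 for SMIM15. With replicate 1 added, the mean of FAT4 was -1.99 as deposited and 0.27 with the sign of replicate 1 turned, and that of MINDY2 was 0.31 and 1.62. Each of the 6 rested on 1 clone, and PTPRG-AS1, MINDY2 and STARD10 on 1 spot. With spots on at least 2 of 3 arrays, PTPRG-AS1 came to 1.18 and STARD10 to -0.89, while the others hardly moved. None of the 6 passed the test (adjusted p = 0.994 for each, limma).

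In part B, PHC3, a component of a Polycomb complex, had the highest mean log2 ratio of one sign, at 1.61 ± 2.25 (SD, n = 2), which came from replicate 2 (3.20) while replicate 3 read 0.01 and replicate 1, as deposited, -4.35. With replicate 1 added, its mean was -0.38 as deposited and 2.52 with the sign of replicate 1 turned. IGFBP7, a secreted protein that binds insulin-like growth factors, followed at 1.51 ± 0.18, with 1.38 on replicate 2, 1.64 on replicate 3 and 0.36 on replicate 1 as deposited. With replicate 1 in place of replicate 2 or 3, its mean fell to between 0.51 and 1.0, and that of SH2D4A, below, came to between -1.02 and -0.58. SEL1L, an adaptor for the degradation of proteins from the endoplasmic reticulum, stood at 1.44 ± 1.91, which came from replicate 2 (2.79), with 0.09 on replicate 3 and -0.38 on replicate 1 as deposited. Without replicate 2 its mean was -0.14, or 0.23 with replicate 1 turned. The lowest means were those of SH2D4A, an SH2 domain protein, at -1.60 ± 0.01, TRAPPC8, a subunit of a vesicle tethering complex, at -1.44 ± 1.42, and LMBR1, a membrane protein, at -1.42 ± 0.51. For SH2D4A the values were -1.59 and -1.61, a 3.03-fold difference, with -0.43 on replicate 1 as deposited. Each of these genes rested on 1 clone, and TRAPPC8 on 1 spot. The adjusted p was 0.852 for IGFBP7 and SH2D4A and 0.865 for PHC3 (limma), so none of these genes passed.

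No feature passed an adjusted p of 0.05 with limma in either part. A feature was a gene, or a spot or clone without a single gene name. In part A, 0 of 14050 features passed, among them 3400 named genes, and the smallest adjusted p was 0.994. At an unadjusted p under 0.05 there were 499 features (3.55%), 245 higher and 254 lower. In part B, 0 of 13335 features passed, among them 3277 named genes, with a smallest adjusted p of 0.852. Here 758 features (5.68%) had an unadjusted p under 0.05, 282 higher and 476 lower. This lean depended on the arrays used: with replicate 1 added there were 123 higher and 438 lower as deposited, and 409 higher and 341 lower with its sign turned. An unadjusted p under 0.05 falls to 5% of unchanged features. The ordinary one-sample test without moderation also passed 0 features, with 619 and 659 at an unadjusted p under 0.05 in parts A and B. With 2 arrays and no moderation, hardly any feature could pass whatever the difference, so its 0 adds little. A dye term that brought in replicate 1 passed 5 features in part A and 11 in part B with its sign as deposited, all lower, and 4 and 5 with its sign turned, all higher.

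**Figure D1:**
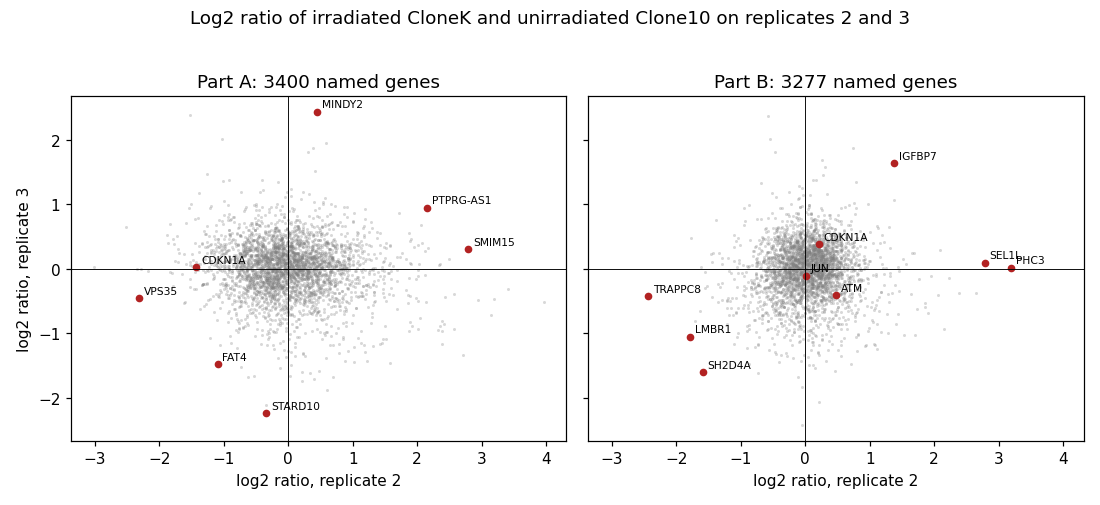
Log2 ratio of each named gene on replicate 2 (horizontal axis) and replicate 3 (vertical axis), with 3400 genes of part A on the left and 3277 of part B on the right. Each grey point is a gene, and red points mark the 3 highest and 3 lowest means of one sign and the preset radiation response genes. The points form clouds without a diagonal, with Pearson r of -0.10 in part A and 0.04 in part B.

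Replicates 2 and 3 showed little or no correlation across features. Across the features of part A, Pearson's r between replicates 2 and 3 was -0.058 (95% interval -0.075 to -0.042). In part B it was -0.0012 (-0.018 to 0.016). Spearman's rho was -0.038 and 0.030. Over the named genes alone, Pearson's r was -0.102 (-0.135 to -0.068) in part A and 0.035 (0.0011 to 0.0695) in part B. Features are not independent replicates. The share of features with one sign on both replicates was 49.0% in part A and 51.8% in part B, where unrelated arrays give 50%. In part A, 58 features lay beyond 2-fold on both replicates with one sign and 95 with opposite signs. The counts in part B were 34 and 68. By the same measure, r between replicates 1 and 2 was 0.101 in part A and -0.163 in part B, and r between replicates 1 and 3 was -0.027 and 0.073.

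By size alone, 319 features of part A had one sign on replicates 2 and 3 and a mean of at least 2-fold, 168 higher and 151 lower, and 40 of them were named genes. In part B there were 191, 81 higher and 110 lower, with 21 named genes. These counts carry no test. They depended on the arrays used. Without replicate 3 and with replicate 1 added, part A gave 739 with the sign of replicate 1 as deposited and 487 with it turned, and part B gave 358 with it turned. Without replicate 2, part B gave 298 with replicate 1 as deposited. With all 3 arrays the counts were 118 and 107 in part A and 70 and 87 in part B, as deposited and turned. The direction was not stable in part B, with 11 higher and 59 lower as deposited and 68 higher and 19 lower turned. Averaging neighbouring spots without a name (by spot number), which was chosen after seeing the data, left fewer features. The counts were then 127 of 8997 in part A and 62 of 8663 in part B. The named genes among them, 40 and 21, could not change, since this averaging leaves their values as they are.

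Among the preset radiation response and repair genes, CDKN1A, JUN and ATM were measured under a single name on all 3 arrays of a part. CDKN1A, which encodes the cell cycle inhibitor p21, had a log2 ratio of -0.70 ± 1.02 (SD, n = 2) in part A, with -1.43 on replicate 2 and 0.02 on replicate 3. In part B it stood at 0.29 ± 0.12, with 0.21 and 0.38. The adjusted p was 0.994 in part A and 0.949 in part B (limma). JUN, an AP-1 transcription factor of the immediate-early response, stood at -0.05 ± 0.08 in part B, where its 3 clones ranged from -0.45 to 0.25. ATM, the kinase that signals double-strand breaks, stood at 0.03 ± 0.63 in part B, with 0.48 on replicate 2 and -0.41 on replicate 3, and at -0.06 with replicate 1 added and turned. Their adjusted p were 0.991 and 0.997 (limma). MDM2, GADD45A, FOS, EGR1, PRKDC and XRCC5 had no such value and were not analysed here.

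Of the immediate-early genes, 8 were measured in part B. This list had the lowest unadjusted p of all lists, 0.0137 (camera in limma), and an adjusted p of 0.219. With an estimated correlation the unadjusted p was 0.238 and the adjusted p 0.976. By fry in limma the unadjusted p was 0.165 and the adjusted p 0.881. In this list 5 members were lower and 0 higher on both replicates, and the median was -0.18 on replicate 2 and -0.39 on replicate 3. IER2 stood at -0.89 ± 0.58 (SD, n = 2) and FOSB, an AP-1 subunit, at -0.65 ± 0.10. In part A, 11 members were measured, 3 were lower and 0 higher on both replicates, and the adjusted p was 0.889, with a median of 0.03 although camera's direction was down. KLF4, a transcription factor, stood at -0.66 ± 0.34, and ZFP36L1, which promotes the decay of AU-rich mRNAs, at -0.25 ± 0.08.

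Genes of double-strand break repair and checkpoint signalling were measured with 11 members in part A and 9 in part B. In part A, 4 were higher and 2 lower on both replicates (adjusted p = 0.889, camera in limma). MRE11, a nuclease of the complex that senses breaks, stood at -0.63 ± 0.19 (SD, n = 2), and RPA1, which binds single-stranded DNA, at 0.49 ± 0.59. Replicate 1 as deposited read 0.75 for MRE11, whose mean with it was 0.13 without replicate 2 and -0.01 without replicate 3. With replicate 1 turned, these means of MRE11 were -0.62 and -0.75. In part B, 2 were higher and 3 lower (adjusted p = 0.961). H2AX, the histone variant phosphorylated at breaks, stood at -0.72 ± 0.08, with 0.71 on replicate 1 as deposited, and WRN, a RecQ helicase, at 0.38 ± 0.12.

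Cell cycle genes were tested in 1 part each. Of 6 genes of G1/S and DNA replication in part A, 2 were higher and 2 lower on both replicates, and the mean of 0.16 and the median of -0.16 had opposite signs (adjusted p = 0.889, camera in limma). RFC5, a subunit of the clamp loader, stood at 1.32 ± 1.66 (SD, n = 2), which came from replicate 2 (2.49), with 0.15 on replicate 3. Without replicate 2 it was 0.20 with replicate 1 as deposited and -0.05 with it turned. CDK6 stood at 0.43 ± 0.30, and its 2 clones disagreed, at -0.06 and 0.91. Of 8 genes of G2/M and mitosis in part B, 3 were higher and 0 lower (adjusted p = 0.749), with BUB1B, a spindle checkpoint kinase, at 0.50 ± 0.09 (0.25 with spots on at least 2 of 3 arrays) and PTTG1, the securin gene, at 0.40 ± 0.03.

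The apoptosis machinery had 6 members in part A and 8 in part B. In part A, 1 was higher and 1 lower on both replicates (adjusted p = 0.889, camera in limma), with BCL2L2, an anti-apoptotic BCL2 relative, at 0.82 ± 0.38 (SD, n = 2) and CFLAR, an inhibitor of caspase 8, at -0.26 ± 0.10. Replicate 1 as deposited read -0.54 for BCL2L2, whose mean with it was 0.01 without replicate 2 and 0.28 without replicate 3. With replicate 1 turned, these means of BCL2L2 were 0.55 and 0.81. In part B, 5 were higher and 2 lower (adjusted p = 0.961), with CYCS, the cytochrome c gene, at 0.46 ± 0.18 and DAXX at -0.39 ± 0.06. Of 7 interferon-stimulated genes in part B, 2 were higher and 3 lower (adjusted p = 0.649), with IFIT5 at -0.72 ± 0.27 and ISG20, an exonuclease, at -0.43 ± 0.19.

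Protein folding and turnover were covered by 3 lists. Genes of the unfolded protein response and ER folding had 1 member higher and 2 lower on both replicates among 5 in part A (adjusted p = 0.889, camera in limma), with SSR1 at -0.83 ± 0.31 (SD, n = 2) and DNAJC3 at 0.65 ± 0.62. In part B they had 3 higher and 2 lower among 6 (adjusted p = 0.649), with SEL1L, given above, and the ER chaperone HYOU1 at 0.57 ± 0.12. Among 5 heat shock proteins and chaperones in part B, CCT4 stood at -0.32 ± 0.32 and DNAJA1 at 0.26 ± 0.15 (adjusted p = 0.961), and the mean of 0.01 and the median of -0.03 had opposite signs. Proteasome and ubiquitin genes had adjusted p of 0.889 among 5 in part A and 0.961 among 6 in part B. PSMD11 stood at -0.62 ± 0.83 in part A, and PSMD5 at 0.42 ± 0.17 and PSME3 at -0.32 ± 0.09 in part B.

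Among spliceosome and RNA-binding proteins, 2 were higher and 3 lower on both replicates among 11 in part A (adjusted p = 0.889, camera in limma), and 5 were higher and 1 lower among 15 in part B (adjusted p = 0.961). The splicing factor TRA2A stood at 0.57 ± 0.41 (SD, n = 2) in part A and at -0.48 ± 0.31 in part B. SF3A1 stood at -0.77 ± 0.86 in part A and SRSF11 at 0.45 ± 0.12 in part B. Histones and chromatin proteins had adjusted p of 0.889 among 8 in part A and 0.649 among 12 in part B. H2AZ2 stood at -0.31 ± 0.15 and HMGB3 at -0.24 ± 0.14 in part A, where HMGB3 came to 0.19 with replicate 1 added and turned. ANP32A stood at -0.70 ± 0.17 (-0.35 with spots on at least 2 of 3 arrays), with 1.34 on replicate 1 as deposited, and H2BC21 at -0.38 ± 0.30 in part B. Among 6 translation factors and tRNA synthetases in part B, EIF3B stood at 0.30 ± 0.20 (0.15 with spots on at least 2 of 3 arrays) and EIF2S2 at -0.30 ± 0.42 (adjusted p = 0.961).

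Of 8 glycolysis and hypoxia-responsive genes in part B, 1 was higher and 3 lower on both replicates (adjusted p = 0.961, camera in limma), with the hexokinase gene HK2 at 0.62 ± 0.11 (SD, n = 2), or 0.41 with spots on at least 2 of 3 arrays, and VEGFA at -0.28 ± 0.04. Of 9 genes of sterol and lipid synthesis, 2 were higher and 3 lower (adjusted p = 0.961), with HMGCS1 at -0.29 ± 0.03 and IDI1 at -0.25 ± 0.19. WNT pathway genes and targets had adjusted p of 0.889 among 7 in part A and 0.961 among 15 in part B, and in both parts the mean and the median had opposite signs. EPHB3 stood at 0.39 ± 0.13 and DVL3 at 0.35 ± 0.07 in part A, where the 2 clones of DVL3 disagreed at -0.17 and 0.88. TNFRSF19 stood at 0.30 ± 0.28 and LEF1 at -0.16 ± 0.17 in part B. Replicate 1 as deposited read -1.27 for TNFRSF19, whose mean was -0.22 with it added and 0.62 with it added and turned. Markers of other cell types, mesenchymal, stromal and endothelial, had adjusted p of 0.889 among 6 in part A and 0.749 among 14 in part B. COL6A3 stood at -0.39 ± 0.17 and PECAM1 at 0.16 ± 0.14 in part A, and COL4A1 at 0.49 ± 0.49 and KDR at -0.45 ± 0.43 in part B. Replicate 1 as deposited read 1.31 for COL6A3, whose mean was 0.18 with it added and -0.70 with it added and turned. The mean of PECAM1 was -0.01 with replicate 1 added and turned.

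**Figure D2:**
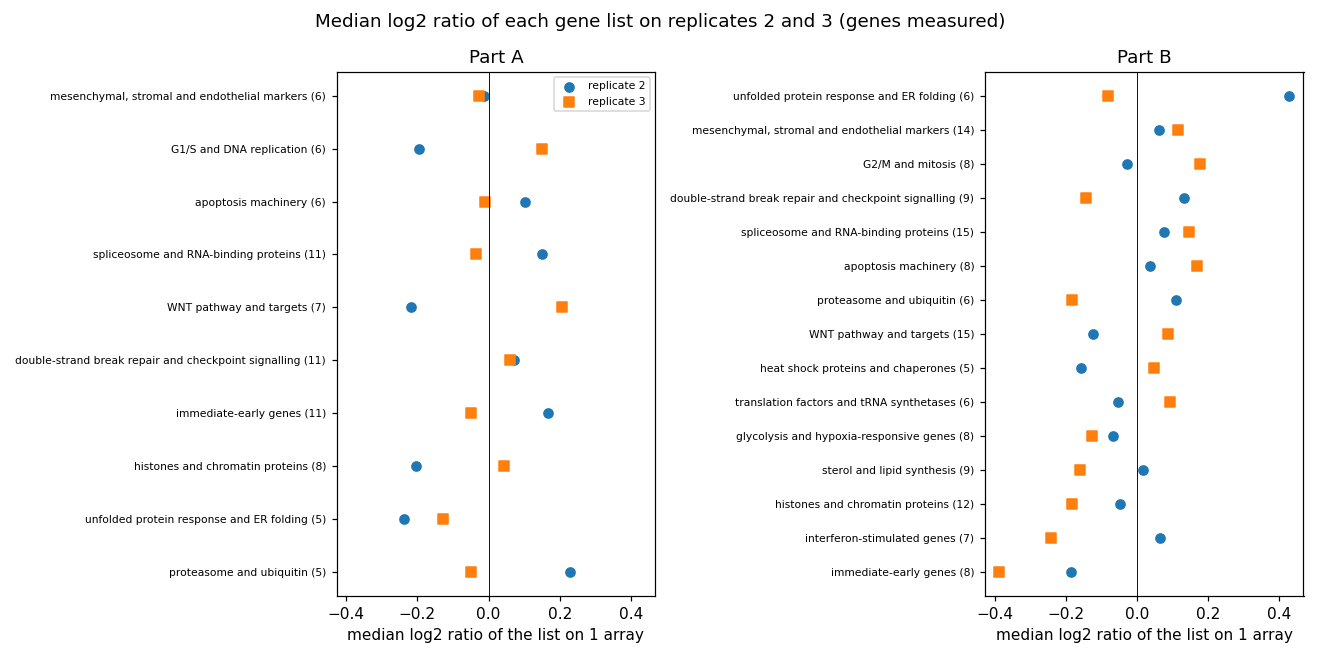
Median log2 ratio (horizontal axis) of the measured genes of each list (vertical axis, number of genes in parentheses) on replicate 2 (blue circles) and replicate 3 (orange squares), for 10 lists of part A and 15 of part B. The medians of both replicates had one sign for 3 of these 10 lists in part A and for 6 of these 15 in part B.

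No list passed the test in either part. In part A 11 lists were tested and in part B 16, with lowest adjusted p of 0.889 and 0.219 (camera in limma). At an unadjusted p under 0.05 there were 0 lists in part A and 1 in part B, the immediate-early genes. By fry in limma, proteasome and ubiquitin genes in part A (unadjusted p of 0.0181) and 1 other list in part B had such a value. The immediate-early genes of part B did not, with an unadjusted p of 0.165 by fry. The lowest adjusted p by fry were 0.199 and 0.506, and those by camera with an estimated correlation were 0.907 and 0.976. No member of any list passed adjusted over all features (0 of 83 memberships in part A and 0 of 143 in part B) or adjusted over the list alone (0 and 0). The 10 other lists, among them excision and mismatch repair, inflammatory mediators, antioxidant genes, ribosomal proteins, oxidative phosphorylation, keratins and intestinal, blood cell and liver markers, had 1 to 4 measured members per part and were not tested.

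No chromosome passed the test in either part. All of the 23 chromosomes tested in each part held at least 35 measured genes, and the mean log2 ratio per chromosome lay between -0.06 and 0.08 in part A and between -0.04 and 0.09 in part B. The lowest adjusted p were 0.952 and 0.951 (camera in limma). The lowest unadjusted p were 0.249 for chromosome 18 in part A, with 61 genes and a mean of 0.08, and 0.161 for chromosome 21 in part B, with 40 genes and a mean of 0.09. By fry, which tests whether the genes of a chromosome move one way, 1 chromosome of part A and 2 of part B had an unadjusted p under 0.05 and 0 passed after adjustment.

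For 527 genes with clones on both parts, the mean log2 ratio of part A did not relate to that of part B. Across these genes, Pearson's r was -0.004 (permutation p = 0.926) and Spearman's rho -0.004 (permutation p = 0.925). Genes are not independent replicates. The family held 12 such relations, and the adjusted p of this one were 0.976 for r and 0.945 for rho. On replicate 3 alone, r was -0.117 (permutation p = 0.00718, adjusted p = 0.0862) and rho -0.130 (permutation p = 0.0027, adjusted p = 0.0324), so rho passed the threshold there and r did not. With replicates 1 (as deposited) and 3, r was -0.087 (permutation p = 0.0481, adjusted p = 0.288) and rho -0.071 (permutation p = 0.105, adjusted p = 0.631).

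The sizes that the design could detect were set with simulated changes in the same features. With 200 features changed 4-fold and 2 arrays, limma recovered 79.7% of them in part A, among 14050 features, and 84.6% in part B, among 13335. Of 2-fold changes it recovered 0.8% and 0%. A 2-fold change of a single gene was therefore rarely or never detectable with these arrays. A log2 shift of 1 in every list member was called in 99.5% of simulated tests in part A and 100% in part B. A shift of 0.5 was called in 73.6% and 92.2%. These shares are for camera at the preset correlation and for genes made unrelated by the shuffling. For lists whose genes vary together they may be too high.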

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

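The averaging of neighbouring spots without annotation, and the addition of replicate 1 to the list and chromosome tests, were chosen after seeing the data. Of 17 settings of the limma fit, the main one included, 15 passed 0 features in part A and 15 passed 0 in part B. The exceptions were the fits with a dye term, which passed 5 features in part A and 11 in part B with replicate 1 as deposited, and 4 and 5 with it turned. In these fits the residual comes from replicates 2 and 3 alone, so the scatter of replicate 1 is not in the spread. Each of the 25 calls, of 17 features, had a larger value on replicate 1 than on the others, at least 3.55 in size. The only named gene among them, ERICH3, was chosen after its values were seen and read -8.30, 0.73 and -0.58 on replicates 1, 2 and 3.

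Without replicate 1, 2 or 3 the counts of calls were 0 throughout. The fit without moderation, also at 0, could hardly pass any feature with 2 arrays. The 2-fold counts of 319 and 191 became 118 and 70 with replicate 1 added as deposited, and 107 and 87 with it turned. Averaging neighbouring spots without annotation left 8997 and 8663 features, of which 127 and 62 were counted. At 1.5-fold the counts were 1859 and 1134. The 2-fold counts ranged from 291 to 739 in part A and from 169 to 358 in part B without replicate 1, 2 or 3. Without replicate 3, part A gave 739 with replicate 1 as deposited and 487 with it turned, and part B 358 with it turned; without replicate 2 and with replicate 1 as deposited, part B gave 298. The cause was not tested. The counts of shifted lists and chromosomes were 0 under every alternative run.

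The correlation between parts was -0.004. It was 0.00351 with replicate 1 added and turned, 0.0305 with spots on at least 2 of 3 arrays, and between -0.0867 and 0.0444 without replicate 1, 2 or 3, where 0.0185 was the value without replicate 1. It was 0.00125, 0.0282 and -0.117 on replicates 1, 2 and 3 alone. Of 1005 values of named genes under alternatives, 78 had the opposite sign, all of them in settings that used replicate 1. Robust eBayes, no moderation and the averaging of unnamed spots could not change these values, so this share understates the changes. In the settings that used replicate 1, between 3 and 16 of 67 values per setting had the opposite sign. Among settings with the same arrays but other spots or another scaling, 6 of 67 values of named genes moved by over 1.5 times in size. Named genes have no value with each spot alone.

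No paired analysis was possible because both RNAs of a comparison lie on the same array, so each ratio already sets 1 RNA against the other, and no groups on different arrays were tested against each other. The number of arrays limits the precision. Signal over background was not used here.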

Other observations

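All tests in this part were chosen after the result was seen, except the first 100 draws with replicate 3 shuffled over the features as analysed in the report and the count after scaling, which were fixed before their values were seen. No biological explanation was tested, since the labels give a single comparison.

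Turning the sign of replicate 3, which the labels rule out, made the limma fit of replicates 2 and 3 pass 71 features in part A, 15 of them named genes, and 0 in part B, where the fit with both as deposited passed 0 in each. With 1 array on either side, this fit takes its spread from the mean of both arrays and also responds to a large value on 1 of them, so its calls are given only as counts. Of the 71, 54 were positive on replicate 2 and negative on replicate 3, and 3 had one sign on both. With neighbouring spots without a name averaged, the fit passed 57 features in part A and 19 in part B. After all arrays were scaled to one median absolute deviation, 1 feature passed. The features at an unadjusted p under 0.05 went from 996 to 937 only, and all 71 stayed among them (limma). Over the 71, the median size of the difference between replicates 2 and 3, divided by 2, was 1.77 before scaling and 1.60 after, with a median SE of 0.42 and 0.38. The prior degrees of freedom of limma fell from 123 to 16, which is a weaker moderation. The medians do not show how the difference against its SE changed for single features. Whether the wider spread of replicate 2 in part A was behind the calls cannot be told apart from that change in moderation.

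Spots with consecutive numbers were taken as neighbouring pairs. These shared 1 clone identifier in all 4109 annotated pairs of part A and all 4156 of part B. Positions on the slide were not used here, so it was assumed that neighbours in number were neighbours on the slide. The spots of a pair resembled each other within an array, with r between 0.395 and 0.545 over the 6 arrays, while the arrays did not resemble each other. After the best choice of signs for the 3 arrays of a part, the lowest pair correlation was still 0.0269 at most over spots, features and named genes. That argues against a turned sign as the whole cause. Shifting one array by 1 to 2400 clones gave at most 0.0878 in size for any pair, between replicates 1 and 3 of part B at a shift of -2400. This lies at the limit of the search. The values argue only against shifts of up to 2400 clones, and larger shifts or another order of the spots were not tried. A turned sign of replicate 1 in part B remains open. Turning it would raise r with replicate 2 to 0.214 over named genes but bring r with replicate 3 to -0.0863. Different pairs with one clone identifier were taken as spots printed apart, whatever their distance. They correlated at 0.0590 at most over the 6 arrays, with upper 95% bounds up to 0.247. Different clones of one gene correlated at -0.0751 to 0.0909. Neighbouring spots of different clones correlated at 0.0972 to 0.236, below the spots of a pair on each array. That argues against local conditions as the whole source of the resemblance within a pair only if consecutive spot numbers are equally close on the slide. The low values for spots printed apart go with local conditions, since a signal of the clone would also be shared by such spots. How much of the resemblance came from local conditions cannot be told from these values. A mismatch between names and spots would also lower the values for spots printed apart and was not tested.

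The number of 2-fold features was set against arrays with no relation. In part A, shuffling replicate 3 over the features gave 348 to 418 features of one sign with a mean of at least 2-fold, above the 319 observed in all 100 of 100 draws. In part B the draws gave 139 to 190 and 0 of 100 reached the 191 observed, against 84 of 10000 further draws, which argues against chance pairing there. With neighbouring spots without a name averaged, however, 62 were observed and 46 of 100 draws gave as many. Counting the spots of a pair as separate may therefore account for the excess in part B. This averaging cannot tell a shared clone from shared local conditions as the source of their resemblance.

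In each part, 1 of the sign patterns that the labels rule out gave more features than either pattern they allow. With 3 arrays and limma, 573 features of part A had an unadjusted p under 0.05 with replicate 1 as deposited and 469 with it turned. With replicate 3 turned there were 867 and with replicate 2 turned 526. In part B the counts were 561 and 750 for the allowed patterns, and 930 with replicate 2 turned and 384 with replicate 3 turned. All 4 patterns passed 0 features after adjustment in both parts.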
